A study of Danio rerio with 12 samples.

How the data were processed

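Poly(A) RNA from zebrafish larvae was sequenced in 12 libraries: 5 solvent controls, 4 at a low dose of broflanilide (1 µg/L) and 3 at a high dose (10 µg/L). Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a directional kit that marks the second strand with dUTP. The submitters' processing notes name fastp, HISAT2, featureCounts, DESeq2 and the build GRCz11, with no versions and no roles. Whether reads were counted by strand is not given in the sources used here, so a gene and an overlapping antisense partner may share reads.

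Each dose had its own table against the same control libraries. Per the file headers, the deposited tables hold raw read counts per Ensembl gene, and these whole-number counts were the starting point here. A second set of columns holds a normalized signal, which for the authors' deposited values equals the count divided by 1 size factor per library and table, as the ratio of the columns was constant within each library. The deposited tables also give the authors' log2 fold change of each dose against the control. The authors' p-value and adjusted p-value stand beside it, and the adjusted values equal Benjamini-Hochberg values over the genes with a p; genes without a p (64 in the low-dose table and 15 in the high-dose table) have an adjusted value of 1. The log2 fold changes and p-values of the authors were used only where the text names the authors' deposited table. Another 17 columns of FPKM were not used. There are 25811 genes at the low dose and 25448 at the high dose, of which 25004 are in both. No gene is at 0 in every library of its table.

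Total counts per library ran from 11721407 to 15491749 in controls, from 10721597 to 16380300 at the low dose and from 11920241 to 13865533 at the high dose. For the median gene, the 95% interval of a log2 fold change reached 0.71 to either side at the low dose and 0.73 at the high dose. The biological coefficient of variation was 39.8% in the low-dose fit and 36.8% in the high-dose fit.

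The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with TMM scaling and a prior count of 0.125, on the deposited counts of genes with a mean count of at least 10. Each dose was fitted with the controls of its own table. The difference between the doses was fitted on all 12 libraries for genes in both tables, where the control counts were identical. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM (counts scaled to a common library total) on 1 TMM scale over all 12 libraries, given as mean ± SD. Log2 CPM for principal components and list scores used a prior count of 1.

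Of 38 gene lists fixed before the data were examined, 37 had at least 5 measured members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists cover neurotransmission, neuronal activity, vision, xenobiotic and energy metabolism, lipids, hormones, stress, immunity and tissue markers. A list score per library is the mean log2 CPM of the members minus the control mean. Named genes followed a rule also set before the data were examined. For each dose these were the largest changes past the threshold among genes with a standard symbol, a mean count of at least 50 and every treated library on 1 side of the control median. With fewer than 10 such genes, the 10 with the smallest unadjusted p were taken, and are described as not past the threshold. Up to 4 members with the smallest p were named per reported list, and GABA-A receptor subunits and cyp1a were named whatever their p; values of 3 of these subunits are not reported here, though every list test includes them. Genes past the threshold in the authors' deposited table were added after their values were seen.

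On simulated counts the low-dose test recovered 15.3% of genes changed 2-fold and 64.5% of those changed 4-fold, over 18472 simulated genes, and 6.25% of its calls were false. The high-dose test recovered 17.3% and 72.4%, over 18294 genes, with 6.38% false calls. Simulated lists were judged at an unadjusted camera p under 0.05, unlike the real lists, which were judged on adjusted p. A list shifted by 0.5 (log2) passed at both doses, and of 20 unshifted lists 0 passed at the low dose and 1 at the high dose. Simulated genes varied independently of each other. In the tested lists the estimated correlation between genes had a median of 0.28 at the low dose and 0.31 at the high dose. The simulation therefore does not give the share of false calls for lists of correlated genes.

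Alternatives were prior counts of 0.5 and 5, no count filter, a mean count of at least 50, DESeq2 size factors, DESeq2 1.42.0, limma with array quality weights, the replicate number as a block, each library left out in turn, and a log2 fold change of at least 1. Recovering reads from normalized values was not needed, because counts are deposited. A robust quasi-likelihood fit and fits without the libraries that stood apart were added after seeing the data. Replicates were compared pairwise before averaging, and the lowest chi-square per degree of freedom within a group was 15.2, so no pair was counted as 1 library. Genes of close families, such as crystallins, opsins, trypsins, myosin heavy chains and heat shock proteins, can share reads with near-identical copies, and their values are uncertain to that extent.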

Results

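Messenger RNA of zebrafish larvae was measured after exposure to broflanilide, a meta-diamide insecticide that blocks GABA-gated chloride channels of insects, or to the solvent DMSO alone. The 12 libraries form 3 groups: control (n = 5), low dose at 1 µg/L (n = 4) and high dose at 10 µg/L (n = 3). Larval age and exposure time are not given in the sources used here. The labels do not say whether libraries came from separate clutches or pools, so p-values measure only the spread between these samples, which may be technical. Total counts per library ran from 10721597 to 16380300.

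Across genes, log2 CPM of the 19 within-group pairs correlated at 0.840 to 0.951. The first principal component held 27.6% of the variance and set control replicate 3 (119) against low dose replicate 4 (-93.0), and the second, with 15.4%, set control replicate 2 (92.7) apart. Low dose replicate 4 was the deepest library (16380300 counts) with the lowest share of mitochondrial counts (4.70%, against 7.08% ± 0.37 in controls, SD, n = 5). The TMM factor of control replicate 3 was 0.814.

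**Figure D1:**
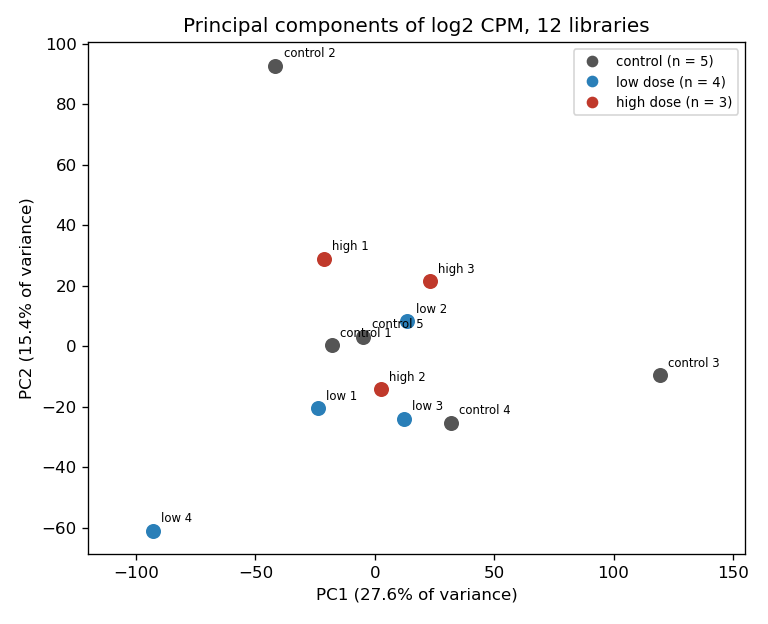
Principal components of log2 CPM for the 12 libraries, with PC1 (27.6% of variance) across and PC2 (15.4%) up; each point is 1 library, coloured by group. Control replicates 2 and 3 and low dose replicate 4 lie away from the other 9 libraries, which mix across groups.

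The low-dose comparison asks which transcripts differ after 1 µg/L. The gene with the smallest p was rps15, which encodes a protein of the small ribosomal subunit (ENSDARG00000070849). It lies on chromosome 11 from 5926850 to 5931622 (plus strand, GRCz11). Its level was 12.7 ± 3.86 CPM (SD, n = 4) against 35.01 ± 10.4 CPM (SD, n = 5) in controls, a log2 fold change of -1.46 (SE 0.28), and 4 of 4 treated libraries lay below every control. With an edgeR adjusted p of 0.924 it did not pass the threshold. In the authors' deposited table rps15 fell by 1.45 on the log2 scale with an adjusted p of 0.0258, and it was the 1 gene past 0.05 there, with 1056 genes at an unadjusted p under 0.05.

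Other genes with the smallest p at the low dose were likewise not past the threshold. Among those with higher values were coq8a, a kinase-like protein of coenzyme Q synthesis (log2 fold change 0.70, SE 0.15), psmd7, a proteasome lid subunit (0.96, SE 0.25), and the inducible chaperone hsp70.3 (2.65, SE 0.73, or 1.34 without low dose replicate 4). The level of hsp70.3 was 17.9 CPM in low dose replicate 4 and between 1.64 and 3.07 CPM in the other low-dose libraries. Also higher were ubap2b (1.296, or 0.85 without that library), txnl1 (0.95) and the elastase CELA1 (1 of many) (1.16). Values were lower for kif15, a mitotic kinesin (-1.06, SE 0.29), for the chromatin protein hmgn6 (-1.92, SE 0.54, or -1.26 without control replicate 1), and for znf362a (-0.55, SE 0.15).

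By edgeR, 0 of 18811 genes passed the threshold at the low dose. At an unadjusted p under 0.05 there were 732 genes (393 higher and 339 lower), or 3.89% of those tested. DESeq2 called 1 gene, rps15, and limma with array quality weights called 0. Without low dose replicate 4 and control replicates 2 and 3, which stood apart, edgeR called 0.

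Of 37 gene lists, 13 passed at the low dose with the preset correlation, 4 upward and 9 downward; with an estimated correlation 0 passed (smallest adjusted p = 0.972). Cell cycle genes were lower in 38 of 41 measured members (median log2 fold change -0.64), including the thymidylate synthase tyms (-2.37), the ribonucleotide reductase subunit rrm2 (-0.98), the replication clamp pcna (-0.74) and fen1 (-0.74). The list score of low dose replicate 4 was -1.58, and the other low-dose libraries lay between -0.61 and -0.19, within a control range of -0.44 to 0.56 except for low dose replicate 1. Phototransduction genes were lower in 36 of 42 members (median -0.26), with gnat2 at -0.63, grk1b at -0.63, guk1b at -0.62 and rcvrna at -0.80. Low dose replicates 3 (-0.59) and 4 (-0.53) scored below the control range of -0.30 to 0.53, and replicates 1 (-0.21) and 2 (0.05) within it. Digestive enzyme genes of the exocrine pancreas were higher in 18 of 20 members (median 0.65), with amy2a at 1.13, cpa1 at 1.11, cpb1 at 1.81 and cel.1 at 0.76; without low dose replicate 4 these were at 0.68, 0.61, 0.46 and 0.49. The estimated-correlation adjusted p was 0.972 for each of these lists, as for every other list called at the low dose. Adjusted over the list alone, 0 members passed in each of the 13 lists except the ribosomal list, and 0 over all genes. The number of lists was 6 without low dose replicate 4, and 7 without that library and control replicates 2 and 3. By fry, which tests whether the genes of a list move one way, 0 lists passed at either dose (smallest adjusted p = 0.943 at the low dose and 0.550 at the high dose).

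Lens genes, mostly crystallins, were higher in 46 of 46 members (median 0.92), among them cryaa (1.70), cryba1l2 (0.97), crygmx (1.51) and crygn1 (0.89). Their score was 2.55 in low dose replicate 4, and without that library the median was 0.02, these 4 genes were at 0.75, 0.49, 0.49 and 0.56, and the call was lost. Circadian genes (median 0.48), such as nr1d4a (1.51), nr1d4b (1.31), tefb (0.88) and ciartb (0.89), had a median of 0.06 without that library and also lost the call, with nr1d4b at 0.20, tefb at 0.39 and ciartb at 0.29. Skeletal muscle genes passed upward with a mean of 0.16 but a median of -0.01, so the median and the test differ in sign; the members with the smallest p were the myosin heavy chains myhz1.2 (0.89), myhz2 (0.77), myhz1.1 (0.57) and myhc4 (1.88, or 0.44 without low dose replicate 4). Of that list the call was lost without control replicates 1 (median 0.03) or 2 (-0.20) and without low dose replicates 2 (-0.10) or 3 (-0.02).

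Lists of energy metabolism and translation passed downward at the low dose. The 13 protein-coding genes of the mitochondrial genome had a median of -0.32, with mt-atp6 at -0.44, mt-nd1 at -0.45, mt-nd3 at -0.50 and mt-nd6 at -0.42. Nuclear genes of oxidative phosphorylation had a median of -0.18, with ndufb7 at -0.47 and ndufs6 at -0.39, while sdhc (1.08) and ndufab1a (1.85) had higher values, the latter -0.64 without low dose replicate 4. In low dose replicate 4, 4.70% of counts were mitochondrial. Ribosomal protein genes had a median of -0.17 and were lower in 68 of 73 members, including rps27a (-0.64) and rpl39 (-0.74), while rpl9 was at 1.14. The gene rpl9 was not among those kept over all 12 libraries, so it has no CPM level and its value is uncertain. Adjusted over the list alone 1 member passed, rps15, against 0 over all genes tested. The oxidative phosphorylation call was lost without control replicates 3 (median 0.02) or 4 (-0.12) or low dose replicates 1 (-0.13) or 4 (-0.05), and the ribosomal call without control replicate 3 (0.04) or low dose replicates 1 (-0.08) or 4 (-0.06).

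Further lists passed downward at the low dose. Pan-neuronal and presynaptic genes had a median of -0.14, with stmn2a at -0.47, stmn2b at -0.60, gap43 at -0.59 and stxbp1b at -0.46; the call was lost without control replicate 2 (median -0.09) or low dose replicate 4 (-0.06). Drug metabolism genes had a median of -0.23, with cyp2x8 at -1.32, cyp2r1 at -0.81 and sult1st6 at -0.78, while the transporter abcb4 was at 0.61; the call was lost without control replicates 3 (-0.12) or 4 (-0.18) or low dose replicate 4 (-0.13). Immediate early genes, which respond to neuronal activity, had a median of -0.43, with egr2a at -1.35, junbb at -0.87, ier2a at -0.74 and nr4a1 at -0.65. That call was lost without control replicates 1 (-0.40), 4 (-0.20) or 5 (-0.26) and without low dose replicates 2 (-0.29) or 3 (-0.19). Hormone and neuropeptide genes had a median of -0.12, with cart4 at -0.89, sst1.1 at -0.40, penkb at -0.38 and adcyap1b at -0.33, and lost the call without control replicates 2 (-0.17), 3 (-0.11) or 4 (-0.12) or low dose replicates 1 (-0.12) or 4 (-0.16). In these 4 lists, 0 members passed adjusted over the list alone or over all genes.

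Other alternatives ended calls at the low dose too. Without low dose replicate 4 and control replicates 2 and 3 these were the mitochondrial genome (median -0.17), circadian (0.08), ribosomal (0.06), oxidative phosphorylation (0.06), pan-neuronal (0.01), drug metabolism (-0.13), skeletal muscle (0.04) and hormone lists (-0.05). Limma with array quality weights ended the circadian (0.14), ribosomal (-0.04), oxidative phosphorylation (0.0062), pan-neuronal (-0.04), drug metabolism (-0.07) and hormone calls (-0.05). The immediate early call was lost with the replicate block (-0.16) and at a mean count of at least 50 (-0.33), the drug metabolism call at that mean count (-0.15), and the hormone call with no low-count filter (-0.26).

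Some named genes of these lists moved by over 1.5 times with 1 library left out. With low dose replicate 4 left out mt-nd3 was at -0.32, mt-nd6 -0.27, ndufb7 -0.25, rps27a -0.41, rpl39 -0.46, gap43 -0.32, stmn2a -0.30 and stmn2b -0.39. Without control replicate 3 mt-nd3 was at -0.32, ndufb7 -0.28, ndufs6 -0.17, rpl39 -0.37 and sst1.1 -0.25. The values of sdhc (0.50), mt-nd3 (-0.75) and mt-nd6 (-0.63) are those without low dose replicate 2. Without control replicate 2 stxbp1b was at -0.31, and without control replicate 4 ier2a was at -0.48.

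GABA-A receptor subunits, the vertebrate relatives of the insecticide's target, did not pass at either dose. The 20 measured subunits had a median log2 fold change of 0.07 at the low dose (adjusted p = 0.612, preset correlation) and 0.07 at the high dose (adjusted p = 0.225), and 0 subunits had an unadjusted p under 0.05 at either dose. At the low dose gabra2a had a log2 fold change of 0.28, gabra3 0.66, gabra4 0.84, gabra5 -0.02, gabra6a -0.53 and gabra6b 0.13. Beta, gamma and delta subunits were at -0.18 (gabrb1), 0.39 (gabrb4), 0.14 (gabrg1) and 0.46 (gabrd). Other subunits were at 0.09 (gabrp), 0.07 (gabrr1), 0.07 (gabrr2a), -0.25 (gabrr2b), -0.18 (gabrr3a), 0.08 (gabrr3b) and -0.47 (gabrz).

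At the high dose the same subunits were at 0.58 (gabra2a), 0.27 (gabra3), 0.30 (gabra4), 0.09 (gabra5), 0.05 (gabra6a) and 0.03 (gabra6b). The others were at -0.44 (gabrb1), 0.09 (gabrb4), 0.35 (gabrd), 0.71 (gabrg1), 0.80 (gabrp), -0.03 (gabrr1), 0.03 (gabrr2a), -0.19 (gabrr2b), 0.31 (gabrr3a), -0.11 (gabrr3b) and -0.21 (gabrz). The subunit list passed upward without control replicate 2 at the low dose (median 0.29) and at the high dose (0.28), and at the high dose without control replicate 1 (0.20). Without control replicate 3 its median was -0.09 at the low dose and -0.08 at the high dose. With an estimated correlation and all libraries its adjusted p was 0.972 at the low dose and 0.997 at the high dose. The level of cyp1a, a monooxygenase induced through the aryl hydrocarbon receptor, was 8.07 ± 5.23 CPM (SD, n = 5) in controls, 13.6 ± 7.34 (SD, n = 4) at the low dose and 10.15 ± 5.21 (SD, n = 3) at the high dose, with log2 fold changes of 0.76 (SE 0.45) and 0.34 (SE 0.49). The low-dose value was 0.31 without low dose replicate 1 and 1.22 without control replicate 3, and the high-dose value ran from -0.14 without high dose replicate 2 to 0.79 without control replicate 3.

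The high-dose comparison asks which transcripts differ after 10 µg/L. The gene with the smallest p was hsp90aa1.2, a cytosolic Hsp90 chaperone gene (ENSDARG00000024746) on chromosome 20 from 53967350 to 53981626 (minus strand). It was at 127 ± 17.1 CPM (SD, n = 3) against 59.5 ± 3.91 (SD, n = 5), a log2 fold change of 1.09 (SE 0.15), with 3 of 3 treated libraries above every control. Next was rps15, at 8.67 ± 2.98 CPM (SD, n = 3), with a log2 fold change of -2.02 (SE 0.31) and 3 of 3 libraries below every control. Their edgeR adjusted p were 0.234 and 0.267, so neither passed. At the high dose 4 genes passed in the authors' deposited table. In the authors' deposited table hsp90aa1.2 rose by 1.07 (log2, adjusted p = 7.52e-06) and rps15 fell by 2.03 (adjusted p = 3.04e-06). For gar1, which encodes a protein of small nucleolar ribonucleoproteins, the authors' deposited table gives a log2 fold change of -3.25 (adjusted p = 0.00688), and for si:ch211-236p5.3 -1.25 (adjusted p = 0.0172).

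**Figure D2:**
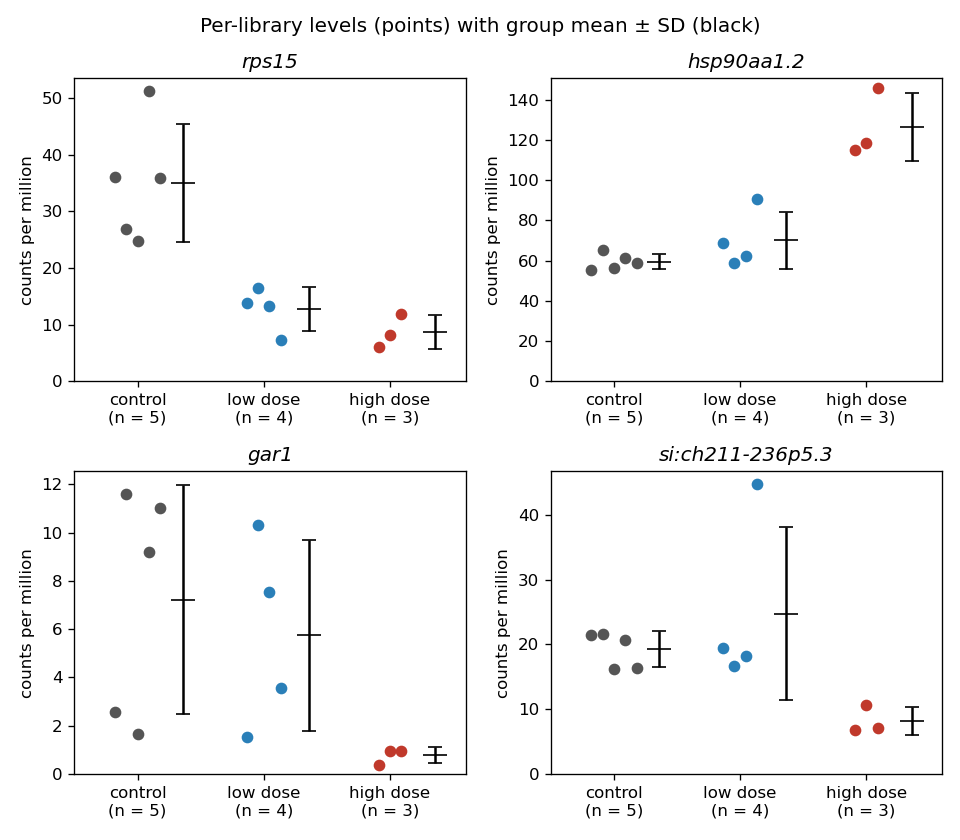
CPM (vertical axis) of rps15, hsp90aa1.2, gar1 and si:ch211-236p5.3 by group; each point is 1 library, and black marks show the group mean with its SD. All treated libraries lie below the lowest control for rps15 (24.8 CPM), and the high-dose libraries lie between 115 and 146 CPM for hsp90aa1.2.

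The level of gar1 (chromosome 14, 43603993 to 43616572) was 0.775 ± 0.328 CPM (SD, n = 3) against 7.21 ± 4.74 (SD, n = 5) in controls, and control libraries ranged from 1.67 to 11.6 CPM. The gene si:ch211-236p5.3 (chromosome 17, 8291561 to 8305792) was at 8.21 ± 2.17 CPM (SD, n = 3) against 19.3 ± 2.74 (SD, n = 5). Neither passed the edgeR threshold. Other genes with the smallest p, also not past it, were the green cone opsin opn1mw2 (log2 fold change 1.05, SE 0.21), the Nogo receptor family gene rtn4rl2a (0.83, SE 0.18), CT573065.1 (0.88, SE 0.18) and the troponin gene tnni2a.1 (1.47, SE 0.38, or 0.98 without high dose replicate 3). Values were lower for the nuclear import receptor ipo8 (-0.72, SE 0.19), nlrp16 (-2.13, SE 0.56) and asb4 (-0.93, SE 0.26). The close paralog hsp90aa1.1, looked at after its values were seen, had a log2 fold change of 0.04 (SE 0.39) at the high dose and 0.96 (SE 0.42) at the low dose, and reads shared between such copies leave both uncertain.

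By edgeR, 0 of 18618 genes passed at the high dose, and 373 had an unadjusted p under 0.05 (200 higher and 173 lower), or 2.00% of those tested. DESeq2 called 4 genes: hsp90aa1.2, rps15, gar1 and si:ch211-236p5.3. Array quality weights in limma gave 2 calls, hsp90aa1.2 and rps15. Without control replicates 2 and 3, which stood apart from the others, edgeR called 1 gene, rps15 (adjusted p = 0.0176); over all alternatives the adjusted p of rps15 ranged from 1.24e-06 with DESeq2 to 1.00.

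Of 37 lists, 9 passed at the high dose with the preset correlation, 7 upward and 2 downward; with an estimated correlation 0 passed. The number of lists was 15 without control replicate 3, 16 without high dose replicate 1, and 9 without control replicates 2 and 3. Genes for plasma proteins secreted by the liver were higher in 27 of 28 members (median 0.96, adjusted p = 0.997 with an estimated correlation). Among them were complement c3a.1 (1.21), prothrombin f2 (1.01), itih2 (1.26) and itih3a (1.11). The list score was 1.39 and 1.54 in high dose replicates 2 and 3 and -0.07 in replicate 1, while controls ran from -1.22 to 1.096. Glucocorticoid and stress genes were higher in 13 of 15 members (median 0.32, adjusted p = 0.415 with an estimated correlation), with the mineralocorticoid receptor nr3c2 at 2.08 (1.38 with a prior count of 5), pomcb at 1.71, tsc22d3 at 0.33 and hsd11b2 at 0.32 (0.19 without high dose replicate 3). Their score was 0.29 to 0.62 in the high-dose libraries against -0.23 to 0.14 in controls. In the low-dose libraries it ranged from -0.13 to 0.81, with the highest value in low dose replicate 4. Levels of nr3c2 (0 to 2.79 CPM) and pomcb (0.10 to 2.67 CPM) were low in all libraries, which leaves their fold changes uncertain. Phototransduction genes were higher in 36 of 43 members (median 0.24, adjusted p = 0.997 with an estimated correlation). These included pde6ga (0.75), opn1sw2 (0.75, or 0.47 without high dose replicate 3) and guca1c (0.53). The phototransduction score was -0.03 to 0.49 in the high-dose libraries, within a control range of -0.30 to 0.53. In that list 1 member, opn1mw2, passed adjusted over the list alone, against 0 over all genes. In the liver and glucocorticoid lists 0 members passed either way.

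Immediate early genes were higher in 23 of 25 members at the high dose (median 0.39), with fosl2 at 0.41, nr4a3 at 0.44, egr3 at 0.47 and fosaa at 0.59. Their score was 0.48 to 0.67 in the high-dose libraries, within a control range of -0.79 to 0.71. Without control replicates 2 and 3 the median was 0.08 and the call was lost. Heat shock and unfolded protein genes had a median of 0.10, with hsp70l at 1.55, dnajb1a at 0.89 and sdf2l1 at -0.37. In that list hsp90aa1.2 alone passed adjusted over the list alone, against 0 over all genes. The call was lost without control replicates 1 (median 0.06) or 2 (0.05), without both control replicates 2 and 3 (0.06), without high dose replicates 2 (0.08) or 3 (0.02), and with limma weights (0.14). Exocrine pancreas genes had a median of 0.30, with pla2g1b at 0.79, cel.1 at 0.51, prss59.2 at 0.46 and prss1 at 0.39. They lost the call without control replicates 1 (0.16) or 2 (0.12) or high dose replicates 2 (0.11) or 3 (0.14). Circadian genes had a median of 0.04, with ciartb at 0.76, nfil3-6 at 0.63, nr1d1 at 0.44 and dbpb at 0.34, and lost it without control replicates 3 (-0.0082), 4 (0.04) or 5 (0.04) or high dose replicates 1 (0.06) or 2 (0.08), with the replicate block (0.15), at a mean count of at least 50 (0.02) and with DESeq2 size factors (0.02). The adjusted p with an estimated correlation was 0.997 for each of these lists. With 1 library left out, dnajb1a was at 0.44 without high dose replicate 2, and fosaa at 0.38 and nr4a3 at 0.29 without high dose replicate 3. Without control replicate 3 pla2g1b was at 1.198, cel.1 at 0.87, prss59.2 at 0.86 and prss1 at 0.79, and without high dose replicate 2 prss59.2 was at 0.06 and prss1 at 0.16.

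Downward at the high dose were ribosomal protein genes, lower in 66 of 72 members (median -0.12), with rps27a at -0.67, rpl13a at -0.81 and rps12 at -0.94, and lens genes, lower in 43 of 46 (median -0.57), with crygm2d3 at -1.54, crygm2d7 at -1.89, crygmxl2 at -1.23 and lim2.5 at -0.93. The crygm genes are close copies of each other, which leaves their values uncertain. Without control replicate 2 crygm2d3 was at -0.72, crygm2d7 at -0.47 and crygmxl2 at -0.44, without control replicate 3 rps12 was at -0.28, and without control replicate 1 rpl13a was at -0.50. Without control replicates 2 and 3, crygm2d7 was at 0.49 and crygmxl2 at 0.38. The ribosomal and lens lists each had an adjusted p of 0.997 with an estimated correlation. In the ribosomal list 1 member, rps15, passed adjusted over the list alone, and 0 over all genes. The ribosomal call was lost without control replicate 3 (median 0.08), without control replicates 2 and 3 (-0.02) or without high dose replicate 1 (0.06). The lens list turned upward without control replicate 2 (0.07) and, without control replicates 2 and 3, passed in the opposite direction (median 0.42); it also lost the call without control replicate 3 (-0.49) and with limma weights (0.13).

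**Figure D3:**
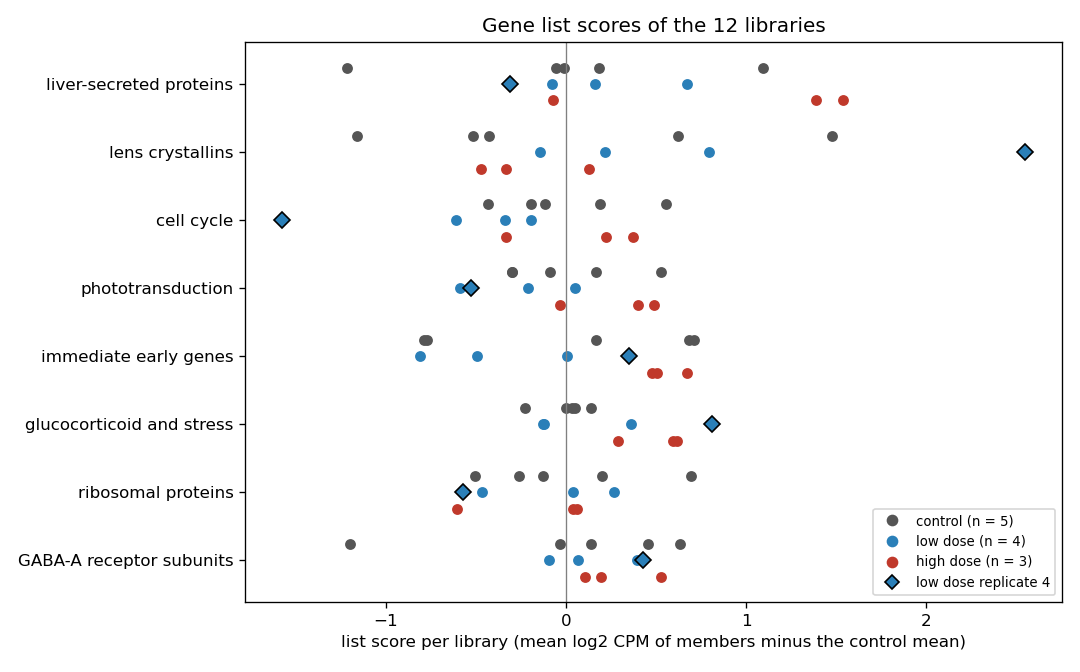
List scores (horizontal axis, mean log2 CPM of the members minus the control mean) for 8 gene lists; each point is 1 library, coloured by group, and diamonds mark low dose replicate 4. That library has the highest lens score (2.55) and the lowest cell cycle score (-1.58), and control scores for the liver list run from -1.22 to 1.096.

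Between the doses, 0 of 18786 genes differed past the threshold by edgeR, 841 had an unadjusted p under 0.05, and DESeq2 called 0. Without low dose replicate 4 and control replicates 2 and 3, edgeR called 3 genes: zgc:122979, nr4a1 and hsp90aa1.2, named here after their values were seen. Of 37 lists, 13 differed with the preset correlation, 10 higher and 3 lower at the high dose, and 0 with an estimated correlation (smallest adjusted p = 0.767). Phototransduction genes were higher at the high than at the low dose in 41 of 43 members (median difference 0.54), cell cycle genes in 39 of 41 (0.60), liver-secreted genes in 28 of 28 (0.93) and immediate early genes in 22 of 25 (0.54). Lens genes were lower in 45 of 46 (-1.55). The number of lists was 23 without high dose replicate 1 and 7 without high dose replicate 3.

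Across 18786 genes, which are not independent replicates, log2 fold changes at the low and high doses correlated at r = 0.327 (covariance 0.0610), with the same controls in both. Simulated unchanged groups against the shared controls gave r = 0.406 (20 runs, 0.381 to 0.425) and a covariance of 0.0856, so the observed minus the simulated covariance was -0.0246. Simulated genes varied independently, unlike those of the real libraries, so the range of these runs cannot show whether the observed value is unusual. With the controls split between the doses, r averaged -0.077 over 20 splits (-0.203 to 0.028). By edgeR 0 genes passed at either dose, so 0 are expected in both lists if independent.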

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

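Tests chosen only after the result was seen are the pan-neuronal comparison for control replicate 3 and all tests of lists between the doses. The patterns examined below, among them the low GABA-A score of control replicate 3, were themselves picked from these data. In the control and low-dose groups, 290 values were examined for 1 library far from the rest of its group, and 33 stood out. Chance gives about 1 in 20, and values of the same library are not independent. The high-dose group was not examined in this way, so nothing is said here about outlying high-dose libraries.

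Low dose replicate 4 accounted for 15 of the 33 values that stood out, with a median correlation of 0.883 with the other libraries (0.934 to 0.942 in the other low-dose libraries). Its levels were high for the pancreas genes amy2a (248 CPM), cpa1 (64.4 CPM), cpb1 (71.0 CPM) and prss1 (1413 CPM). It was also high for the crystallins crygmx (325 CPM) and crygm2d7 (20.6 CPM), for nr1d1 (614 CPM), nr1d4b (26.0 CPM), myhc4 (246 CPM), hsp70.3 (17.9 CPM), ndufab1a (16.9 CPM) and si:ch211-236p5.3 (44.8 CPM). It was low for itih3a (2.62 CPM) and for the glycine receptor list, with a score of -1.04.

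Control replicate 3 stood apart for 6 values: high for rps12 (351 CPM), mt-nd3 (1717 CPM), stmn2a (387 CPM), ndufs6 (94.9 CPM), sst1.1 (55.9 CPM) and itih3a (7.83 CPM). Control replicate 2 did so for 6: high for gabrr2a (33.0 CPM), nr1d1 (336 CPM), crygm2d3 (86.9 CPM), crygm2d7 (21.7 CPM) and the pan-neuronal list (score 0.23), and low for myhz1.2 (689 CPM). Low dose replicate 1 was high for cyp1a (24.5 CPM), dnajb1a (6.71 CPM) and itih2 (23.9 CPM). Control replicate 5 was the deepest control (15.5 M counts) and high for opn1sw2 (37.9 CPM), and control replicate 1 was high for hmgn6 (24.4 CPM).

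The high and low doses differed, with the preset correlation, in 13 lists. The median differences (high minus low, log2) were -1.55 for lens genes, -0.30 for circadian and -0.25 for exocrine pancreas genes. They were 0.93 for liver-secreted, 0.60 for cell cycle, 0.54 for phototransduction, 0.54 for immediate early, 0.32 for hormone and neuropeptide, 0.29 for mitochondrial genome and 0.22 for pan-neuronal genes. Smaller differences were 0.15 for oxidative phosphorylation, 0.14 for cartilage and bone and 0.10 for TCA cycle and glycolysis genes. Of the 35 splits of the 7 treated libraries, 24 gave at least 13 lists and the highest other split gave 22, so chance cannot be excluded. With an estimated correlation 0 of these lists passed.

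Some of these differences were lost under alternatives. Without low dose replicate 4 these were circadian (-0.02), pancreas (0.03), TCA and glycolysis (0.06), oxidative phosphorylation (0.01) and cartilage genes (-0.01). Without high dose replicate 3 they were mitochondrial genome (0.18), hormone (0.12), circadian (-0.21), TCA and glycolysis (0.0044), oxidative phosphorylation (-0.0048) and cartilage genes (0.09). Without high dose replicate 2 they were circadian (-0.35), TCA and glycolysis (0.12), oxidative phosphorylation (0.11) and cartilage genes (0.12), and without high dose replicate 1 pancreas genes (-0.09). Without low dose replicate 1 they were hormone (0.27), TCA and glycolysis (0.11), oxidative phosphorylation (0.10) and cartilage genes (0.12), without replicate 2 cartilage genes (0.12), and without replicate 3 TCA and glycolysis genes (0.16). Leaving out control replicate 3 ended the cartilage call (0.14), control replicate 4 the TCA and glycolysis (0.099), oxidative phosphorylation (0.15) and cartilage (0.14) calls, and control replicate 5 these (0.096, 0.14 and 0.14) and the circadian call (-0.30). With the replicate block hormone (0.25), pancreas (-0.07), circadian (-0.09), oxidative phosphorylation (0.09) and cartilage genes (0.11) lost the call. Without 3 outlying libraries pancreas (0.03), circadian (-0.02), TCA and glycolysis (0.06), oxidative phosphorylation (0.01) and cartilage genes (-0.01) did, and with the 7 treated libraries alone circadian (-0.30) and cartilage genes (0.14).

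At the low dose 13 lists passed. Without low dose replicate 4 the number was 6, so this 1 outlying library may account for part of the calls. Of 100 splits of the 9 libraries, 65 gave at least 13 lists and the highest other gave 27, so chance is not excluded either. A response to the dose stays open and cannot be separated from these by the list counts.

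The GABA-A receptor list scored -1.20 in control replicate 3, against -0.03 to 0.63 in the other controls; glutamate receptors (-0.73) and GABA synthesis and transport (-0.74) were also lowest there among controls, so the low score was not particular to these subunits. A trend with gene length was argued against: with it removed the score was -1.30 (standard error over members 0.17). A smaller share of nervous tissue, lowering all neural genes alike, was argued against by the pan-neuronal list, which scored -0.043 there (standard error 0.08), but liver-secreted (1.096), exocrine pancreas (1.102), intestine (0.76), skin keratin (0.71) and skeletal muscle genes (0.64) had their highest control scores in that library, so another difference in tissue make-up stays open. Fewer reads from genes with a long genomic span, as unspliced RNA would give, were examined too. The deviation of control replicate 3 had a rank correlation of -0.32 with span over all genes. The median span was 46351.5 nt in the GABA-A list and 17422 nt over all genes. With the average trend removed the score was -1.06 (standard error 0.15), so that average trend accounted for a small part. An effect stronger in these genes than on average was not tested and stays open. Apart from the share of nervous tissue, no biological explanation was tested, because the design separates no groups within the controls.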

How the results depend on the processing

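Alternatives chosen only after the data were seen are the fits without outlying libraries, the robust fit, DESeq2 between the doses and all tests of lists between the doses. Of the named-gene values over all alternatives, 2567 kept their direction and side of the threshold, 79 turned sign and 8 newly passed. No named gene passed in the main test, so none could lose a call, and keeping the side meant staying short of the threshold. Another 700 values were those of the lists called with all libraries and of the GABA-A, glycine and aryl hydrocarbon receptor lists. Of these, 514 kept direction and side, 126 lost the call without turning and 3 newly passed. A further 35 turned on the same side of the threshold, and 22 turned and lost the call. Other lists that passed only under an alternative are not among these values, and count only in the numbers of lists. For a list, turned means that the sign of the median or the direction of the test differs. The edgeR gene counts stayed at 0 at either dose under other filters and size factors, the robust fit and each library left out. Between the doses the counts stayed at 0 with the 7 treated libraries alone, with DESeq2 and with each library left out. Other prior counts and a log2 fold change of at least 1 also gave 0, but could not have raised the count. A prior count alters the log2 fold change and not the p-value, so it cannot move a gene or list call. The fold change minimum only removes genes. The median half-width of a 95% interval was 0.71 at the low dose and 0.73 at the high dose; depth was not varied, so what it limits was not tested, and the cause of the changes listed here was not tested. An edgeR test on recovered reads was not run, because counts are deposited.

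DESeq2 called 1 gene at the low dose and 4 at the high dose, and limma with array quality weights 0 and 2. Without the outlying libraries edgeR called 0 at the low dose, 1 at the high dose and 3 between the doses. With an estimated correlation 0 lists passed at the low dose, 0 at the high dose and 0 between the doses. At the low dose 8 lists passed with limma weights and 7 without 3 outlying libraries. With 1 library left out, lists numbered 6 to 17 at the low dose, 8 to 16 at the high dose and 7 to 23 between the doses. The correlation of the dose effects was -0.077 with split controls.

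Same-numbered libraries deviated together at r of -0.258 to 0.260, so the numbers were not taken to pair the samples. For control replicates 1 and 3 the closest treated library at each dose had the same number (r of 0.165 to 0.260). For control replicates 2 and 4 it did not (r of -0.258 to -0.021). Whether the numbers pair some samples is therefore not settled. With the replicate block 0 genes passed in each comparison, and 13 lists at the low dose, 12 at the high dose and 9 between the doses. These are not all the same lists: the block ended the calls of the immediate early list at the low dose (-0.16), of the circadian list at the high dose (0.15) and of 5 lists between the doses. The block turned the signs of gabra5 (0.12), gabrp (-0.26), gabrr3a (0.28) and of the median of the skeletal muscle list (0.31) at the low dose. At the high dose it turned gabra6a (-0.098), gabrr1 (0.038), gabrr2a (-0.037) and gabrz (0.35), and the glycine receptor list gave -0.11.

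Without 3 outlying libraries these turned at the low dose: ribosomal list (0.059), oxidative phosphorylation list (0.056), pan-neuronal list (0.014), GABA-A list (-0.12), glycine receptor list (-0.053), skeletal muscle list (0.042) and gabra2a (-0.24). The same fit turned gabra6b (-0.35), gabrb4 (-0.044), gabrr1 (-0.27), ndufab1a (-0.80) and si:ch211-236p5.3 (-0.11). Limma weights turned oxidative phosphorylation list (0.0062), skeletal muscle list (0.15), GABA-A list (-0.012), gabra2a (-0.033), gabra5 (0.046), gabra6b (-0.20) and gabrr1 (-0.22) there, no low-count filter the aryl hydrocarbon receptor list (-0.071), and DESeq2 size factors the skeletal muscle list (0.000631). At the high dose, leaving out 2 outlying libraries turned lens list (0.42), glycine receptor list (0.23), gabra5 (-0.11), gabra6b (-0.14) and gabrb4 (-0.21). It also turned gabrr1 (0.062), gabrr3b (0.089), crygm2d7 (0.49) and crygmxl2 (0.38). Limma weights at the high dose turned lens list (0.13), glycine receptor list (0.087), gabra5 (-0.19), gabra6b (-0.059), gabrb4 (-0.041) and gabrr1 (0.045). DESeq2 size factors turned the glycine receptor list there (-0.033). Between the doses, the fit without 3 outlying libraries turned the test of the circadian list (median -0.024) and the medians of the exocrine pancreas (0.025) and cartilage lists (-0.010).

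With 1 library left out, the direction of a value or of its list test turned for these at the low dose, given as ranges: ribosomal list (-0.37 to 0.042), oxidative phosphorylation list (-0.31 to 0.022), skeletal muscle list (-0.20 to 0.22), GABA-A list (-0.10 to 0.29), glycine receptor list (-0.16 to 0.0096), aryl hydrocarbon receptor list (-0.028 to 0.16) and gabra2a (-0.21 to 0.61). Others at the low dose were gabra5 (-0.20 to 0.17), gabra6b (-0.17 to 0.30), gabrg1 (-0.10 to 0.40) and gabrp (-0.38 to 0.43). Further ranges there were gabrr1 (-0.36 to 0.35), gabrr2a (-0.27 to 0.49), gabrr3a (-0.42 to 0.10), gabrr3b (-0.076 to 0.42), ndufab1a (-0.64 to 2.21) and si:ch211-236p5.3 (-0.091 to 0.51). At the high dose such ranges were ribosomal list (-0.26 to 0.079), circadian list (-0.0082 to 0.19), lens list (-0.80 to 0.068), GABA-A list (-0.10 to 0.28), glycine receptor list (-0.10 to 0.21), aryl hydrocarbon receptor list (-0.067 to 0.19) and cyp1a (-0.14 to 0.79). Others at the high dose were gabra3 (-0.011 to 0.78), gabra5 (-0.71 to 0.42), gabra6a (-0.14 to 0.32), gabra6b (-0.20 to 0.18) and gabrb4 (-0.25 to 0.39). Further high-dose ranges were gabrp (-0.51 to 1.24), gabrr1 (-0.21 to 0.25), gabrr2a (-0.12 to 0.45), gabrr2b (-0.67 to 0.19) and gabrr3b (-0.50 to 0.23). Between the doses the test direction or sign turned for the circadian list (-0.48 to -0.023), oxidative phosphorylation list (-0.0048 to 0.30), cartilage list (-0.011 to 0.34) and exocrine pancreas list (-0.44 to 0.026).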

Other observations

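The gene rps15 was singled out by its values in these data, so tests of it were not independent of them. The region around rps15 was examined only after its values were seen. For the other tests in this part the criteria were set before the test was run.

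Lists that passed at neither dose cover much of larval physiology. Median log2 fold changes at the low and the high dose were 0.08 and 0.06 for aryl hydrocarbon receptor targets, -0.08 and 0.05 for antioxidant genes, 0.17 and -0.15 for interferon genes, and -0.07 and -0.05 for innate inflammation genes. Apoptosis genes were at -0.02 and -0.03. Metabolic lists were at 0.0020 and 0.05 for cholesterol synthesis, -0.04 and 0.17 for lipid synthesis and lipoproteins, -0.04 and -0.0088 for fatty acid oxidation, and -0.04 and 0.08 for TCA cycle and glycolysis. Bile acid and steroid genes were at -0.03 and 0.27, and thyroid axis genes at -0.15 and 0.03. At the low dose the median differs in sign from the mean or the test for the interferon, intestine, lipid, bile acid, thyroid, cholesterol, antioxidant, fatty acid, liver and TCA cycle lists. At the high dose it does so for the skeletal and cardiac muscle, fatty acid, cholesterol, cartilage, glycine receptor, intestine and GABA synthesis lists.

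Neural and tissue lists outside the calls showed medians of 0.03 and -0.10 for glutamate receptors, 0.16 and 0.0053 for GABA synthesis and transport, -0.08 and -0.01 for glycine receptors, and -0.0032 and 0.03 for glia and myelin. Skin keratins were at -0.03 and -0.13, cartilage and bone at -0.12 and -0.09, cardiac muscle at 0.17 and -0.03, erythrocyte genes at -0.23 and -0.13, and intestine at 0.02 and -0.04. Control libraries alone spanned -1.34 to 0.71 in the skin keratin score and -1.38 to 0.64 in the skeletal muscle score, with control replicate 2 lowest in both.

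The gene rps15 was lower at both doses, in 7 of 7 treated libraries below every control. A trend with gene length was argued against: with it removed the lowest control still lay 0.44 (log2) above the highest treated library, and mean differences were -1.43 and -2.03, against -1.47 and -2.01 before. A region-wide difference in parental background cannot be told apart from a dose response: the median absolute log2 fold change of the neighbours within 300 kb lay at the 82.3 percentile of other windows at the high dose (18 genes) and at the 68.5 percentile at the low dose (19 genes). Complete separation on its own may arise by chance, since 34 of 18786 genes (0.181%, against 0.253% by chance) did not overlap and 46 of 100 splits gave as many, the highest other 535. That count ignores the size of the gap, so a response of rps15 to broflanilide stays open as a hypothesis.

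A count of 0 says nothing about chance, since every split gives at least as many: 100 of 100 drawn at the low dose, 56 of 56 at the high dose and 35 of 35 between the doses, with 1, 19 and 1 in the highest others. For genes at an unadjusted p under 0.05, 32 of 100 splits gave at least 732 at the low dose (highest other 3550) and 39 of 56 gave at least 373 at the high dose (highest other 3388), so chance is not excluded for these counts. For gene lists at the high dose, 45 of 56 splits gave at least 9 and the highest other gave 29, so it is not excluded there either. The split with 3550 genes set control replicates 1 and 2 and low dose replicates 1 and 4 against the rest, and that with 3388 set apart control replicates 1 and 2 and high dose replicate 1. Such counts, several times the real ones, point to a structure of the samples, but these splits were picked for their size, and neither that structure nor its alternatives were tested.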
